A study of Mus musculus with 12 samples.

How the data were processed

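The values analysed were log2 probe set values with 2 decimals, as deposited by the authors in a table of 41345 probe sets by 12 arrays. The submitters' notes name Affymetrix Expression Console for the processing. Its version, the summary method and the normalization are not given in the sources used here. The table had no missing values, and its range and array medians were checked for a log2 scale. No raw image or intensity data were used here. The arrays were grouped by their labels into EtOH, 4OHT, EtOH_Rosi and 4OHT_Rosi, with 3 arrays each. The labels give no dates or batches and do not say whether replicates with 1 number belong together.

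Of the probe sets, 190 were AFFX controls, 16010 had no gene assigned, 1814 had several gene symbols and 23521 had 1. Of the last, 23328 were matched by Entrez ID to a RefSeq gene table, from which current names and the order of neighbouring genes were taken, and 193 kept the name of the probe table. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over the 12 arrays was used, which left 22180 genes. No filter on dim genes was applied. Array signal, not depth, limits these data: the median level of the tested genes was 6.60, the lowest value 3.05, and fold changes of genes near the floor are compressed.

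Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays, followed by eBayes, with 8 residual and 5.07 prior degrees of freedom. The 5 contrasts were 4-hydroxytamoxifen against ethanol without rosiglitazone and with it, rosiglitazone against none after ethanol and after 4-hydroxytamoxifen, and the difference between the 4-hydroxytamoxifen effects (the interaction). Genes at a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called, with no fold minimum. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

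The 29 gene lists, written from general knowledge of the pathways and cell types, were tested with limma's camera with a preset correlation of 0.01, adjusted over the 29 lists within a contrast. Each was tested again with the correlation estimated from the residuals of its own genes, and with fry. Members with no probe set of a single gene symbol were not tested, among them Oas1a and Gbp2 of the interferon-stimulated genes. Adjusted over the list alone means that the Benjamini-Hochberg step was run over the measured members only. Where leaving out 1 array moved a list's count by no more than 1 gene, the array is mostly not named. The groups, contrasts, thresholds, lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

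Genes were named by a fixed rule. It took Prdm16 in every comparison, and for each contrast the 6 largest rises and 6 largest falls among called genes. These needed a higher group mean at or above the median level and, outside the interaction, arrays of the groups compared that did not overlap. Predicted genes, small RNAs and olfactory or vomeronasal receptors were passed over. The rule added up to 4 members of each list with the smallest p, and the panel Ucp1, Cidea, Ppargc1a, Pparg, Adipoq, Fabp4, Irf7, Isg15 and Ifit1. A further item of the panel is not reported here.

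The alternatives were a replicate block, a fit of only the 2 groups compared, an intensity trend with robust eBayes, array weights, quantile normalization, median centring, filters at the 25th and 50th percentile of the mean level, the mean of all probe sets per gene, all probe sets, a 2-fold minimum, and leaving out each array in turn. The counts of list members and of neighbours of Prdm16 called without each array were added after seeing the data. Where an array is left out, its group keeps 2 arrays, and the variance is pooled over all groups.

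The steps were tested on simulated data of the same size, in which 200 genes per contrast were changed. Of genes changed by 0.5 log2, 74.6% to 85.1% were recovered in the comparisons of 2 groups and 50.7% in the interaction. For a change of 1 log2 the shares were 97.0% to 100% and 89.6%, and for 2 log2 all were recovered. Between 4.53% and 6.12% of calls fell on unchanged genes. A list of 50 genes shifted by 0.5 log2 was recovered in each contrast with the preset and the estimated correlation. The simulated genes varied independently of one another. This step therefore does not show how either list test performs where genes are correlated, as they may be in the real lists.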

Results

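The data are 12 Affymetrix expression arrays of adipocytes grown from mouse inguinal fat precursors, in 4 groups of 3. The cells came from mice with a Cre recombinase at the Rosa26 locus and a floxed exon of Prdm16, a transcriptional regulator known for its part in the brown and beige fat program. Growing precursors received 1 uM 4-hydroxytamoxifen, a ligand used to switch on inducible Cre, or its ethanol vehicle for 3 days. They were then differentiated without or with 1 uM rosiglitazone, an agonist of the nuclear receptor PPARgamma. The groups are named EtOH, 4OHT, EtOH_Rosi and 4OHT_Rosi, each with arrays numbered 1 to 3. The 41345 probe sets had log2 values between 3.05 and 13.91, and the arrays had medians between 5.97 and 6.05. For arrays, the number per group limits the precision, and no label says that the replicates are separate cultures. The p-values below therefore measure the spread between these arrays, which may be technical.

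Among the 22180 genes tested, arrays of 1 group correlated at a Pearson r of 0.996 to 0.998 across genes, and arrays of different groups at 0.981 to 0.996. The first principal component held 60.9% of the variance and separated the 6 rosiglitazone arrays from the other 6. The second held 14.3% and separated the 6 arrays given 4-hydroxytamoxifen from the 6 given ethanol. On the third, which held 5.67%, 4OHT_Rosi 3 stood apart at 16.03, while the other arrays lay between -8.95 and 7.97. Fold changes are given on the log2 scale with limma's standard error, for 3 arrays in each group, and adjusted p-values are Benjamini-Hochberg over all genes tested.

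Prdm16 was measured first, as the targeted gene. In the brighter of its 2 probe sets (17433631), its log2 value was 6.63 ± 0.19 (SD, n = 3) in EtOH, 6.46 ± 0.13 in 4OHT, 7.37 ± 0.14 in EtOH_Rosi and 6.65 ± 0.04 in 4OHT_Rosi. Rosiglitazone raised it after ethanol (0.74 ± 0.10, adjusted p = 5.43e-05). With rosiglitazone it fell after 4-hydroxytamoxifen (-0.71 ± 0.10, adjusted p = 0.000646), and all 3 treated arrays lay below the 3 ethanol arrays. Without rosiglitazone the difference was -0.17 ± 0.10 (adjusted p = 0.455), and the arrays overlapped. The difference between those effects was -0.54 ± 0.14 (adjusted p = 0.0954). Without EtOH_Rosi 1 it was -0.63 and its adjusted p was 0.0458. The dim second probe set, with group means from 4.63 to 4.80, passed in no comparison. Where either probe set lies relative to the floxed exon is not given in the sources used here, so neither level measures the excision.

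**Figure D1:**
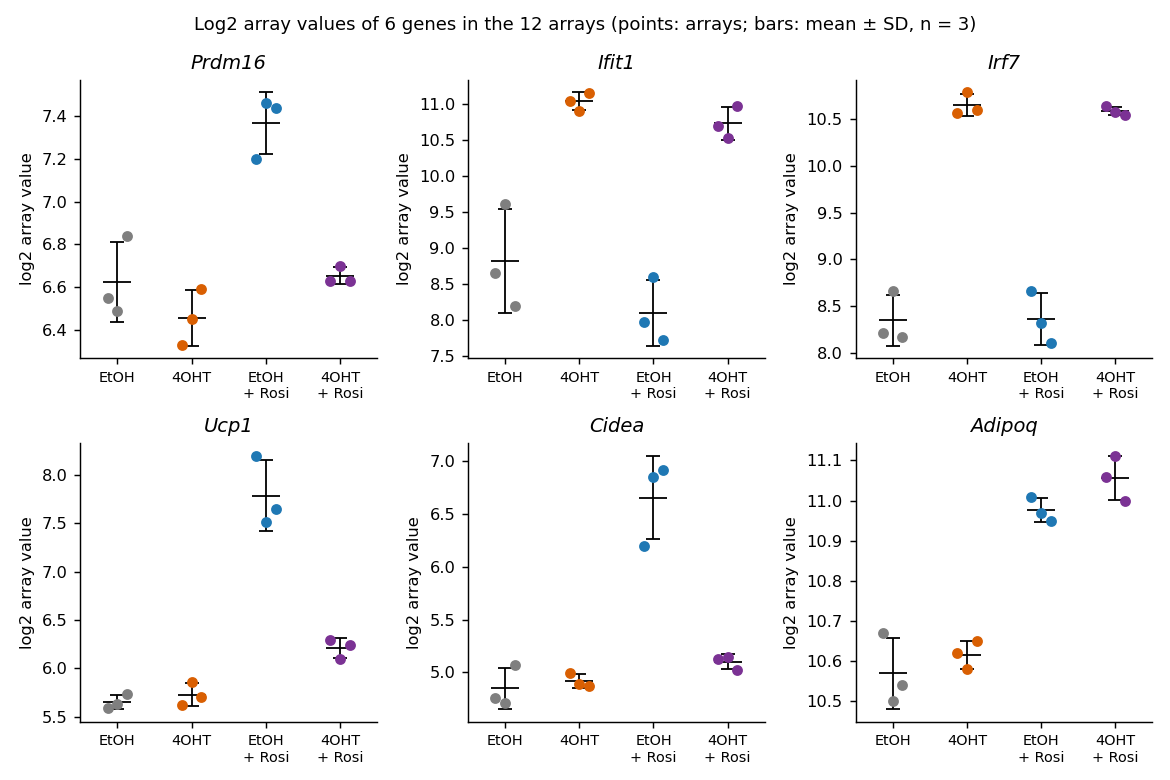
Log2 array values (vertical axes, which do not start at 0 and differ between panels) of Prdm16, Ifit1, Irf7, Ucp1, Cidea and Adipoq in the 4 groups. Points are arrays, and bars give the mean and SD of 3 arrays. Ifit1 and Irf7 lay higher in all 4-hydroxytamoxifen arrays, while Ucp1 averaged 7.79 ± 0.36 in EtOH_Rosi and 6.21 ± 0.10 in 4OHT_Rosi.

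The first comparison asked what 4-hydroxytamoxifen treatment of the floxed precursors changed in adipocytes made without rosiglitazone. Interferon-stimulated genes, the antiviral and antigen-handling genes that interferons switch on, made up most of the largest rises. Of this list 49 of 54 rose and 0 fell (51 and 0 adjusted over the list alone), with a median of 0.98. Irf7, the transcription factor that amplifies the type I interferon response, rose 4.95-fold (2.31 ± 0.14, adjusted p = 4.01e-06). The antiviral genes Ifit1 (2.22 ± 0.29, adjusted p = 0.000617), Mx2 (2.01 ± 0.21, adjusted p = 0.000125) and Cmpk2 (1.95 ± 0.23, adjusted p = 0.000382) rose too, with Apol9b (2.30) and the oligoadenylate synthetase gene Oas1g (2.06). These were the 6 largest rises under the fixed choice of genes, which passed over dim and predicted genes. Oas3 (1.32), Gbp3 (1.58), the RNA sensor Ifih1 (1.15) and the ubiquitin-like modifier Isg15 (1.23) rose as well. Genes ranked by fold change in the comparisons of 2 groups were taken only if the 3 arrays of one group lay above the 3 of the other, which chance gives in 10% of genes.

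In the MHC class I antigen presentation list 14 of 17 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.40. Tap1, a subunit of the peptide transporter, rose by 0.77 ± 0.07 (adjusted p = 5.07e-05), H2-T23 by 0.86 ± 0.08 (adjusted p = 8.15e-05) and H2-Q4 by 0.64 ± 0.08 (adjusted p = 0.000703). Both lists passed camera with the preset correlation (adjusted p = 4.7e-75 and 1.28e-22) and with an estimated correlation (adjusted p = 0.0142 for both). Of the receptors, kinases and sensors of the type I interferon pathway itself, 3 of 26 rose and 0 fell (3 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.384). Its clearest rise was in Tlr3, the double-stranded RNA receptor (0.52 ± 0.08, adjusted p = 0.0016). The count of 3 was 1 without EtOH 2, EtOH 3, 4OHT 1, 4OHT 2 or 4OHT 3. The chemokine gene Ccl5 rose (1.78 ± 0.15, adjusted p = 3.08e-05), as 1 of 25 genes in the NF-kappaB and inflammatory cytokine list, whose median was -0.02 (list adjusted p = 0.858). Macrophage and leukocyte markers had a median of -0.12: 1 of 18 rose and 3 fell (1 and 6 adjusted over the list alone). That list passed with the preset correlation (adjusted p = 0.00761), but adjusted p = 0.619 with an estimated correlation, and it did not pass without EtOH 1 (median -0.043, adjusted p 0.420) or 4OHT 3 (median -0.074, adjusted p 0.101). Without EtOH 3 the median was -0.203. Its count of 3 falls was 1 without EtOH 1, EtOH 2 or EtOH 3 and 0 without 4OHT 2 or 4OHT 3.

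Cell cycle genes were lower after 4-hydroxytamoxifen without rosiglitazone: 0 of 28 rose and 20 fell (0 and 24 adjusted over the list alone), with a median of -0.39 (adjusted p = 2.06e-27, and adjusted p = 0.0706 with an estimated correlation). The proliferation marker Mki67 fell by 0.79 ± 0.10 (adjusted p = 0.0004), the mitotic kinase gene Plk1 by 0.78 ± 0.09 (adjusted p = 0.000249) and cyclin A2, Ccna2, by 0.81 ± 0.12 (adjusted p = 0.00117). Without 4OHT 1 the count of falls was 11. Glycolysis and hypoxia genes also shifted down (0 of 22 rose and 4 fell, or 0 and 12 adjusted over the list alone, median -0.18, adjusted p = 4.7e-09, and adjusted p = 0.163 with an estimated correlation). They included the glucose transporter Slc2a1 (-0.42 ± 0.05, adjusted p = 0.000617). Its 4 falls became 1 without 4OHT 2 and 2 without 4OHT 3. The largest falls under the same choice were in Reg1 (-2.31 ± 0.32, adjusted p = 0.000905), the neurotrophin receptor Ngfr (-2.29 ± 0.16, adjusted p = 1.28e-05), Kng2 (-1.43), the secreted Wnt modulator Sfrp4 (-1.20), the metalloproteinase Mmp12 (-1.12) and the interleukin-4 receptor Il4ra (-1.10).

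Of the brown and beige thermogenic list 1 of 30 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of -0.005 that turned positive under quantile normalization and median centring and a mean of 0.03 (list adjusted p = 0.748). Ucp1, the uncoupling protein of brown fat, differed by 0.08 ± 0.14 (adjusted p = 0.867) and Cidea by 0.07 ± 0.15 (adjusted p = 0.895). Both were dim already in EtOH, where Ucp1 lay between 5.59 and 5.73 and Cidea between 4.71 and 5.07. These levels are below the median of the tested genes, 6.60, so a fall may have been hard to measure. No detection level was set, so this limit was not tested. The general adipocyte list, in which 5 of 33 rose and 1 fell (11 and 2 adjusted over the list alone), had a median of 0.09 (adjusted p = 0.00211, and adjusted p = 0.517 with an estimated correlation). Its 5 rises became 1 without EtOH 2, EtOH 3, 4OHT 1 or 4OHT 2 and 3 without 4OHT 3. Adiponectin, Adipoq, differed by 0.05 ± 0.06 (adjusted p = 0.8) and the lipid carrier Fabp4 by less than 0.01 (adjusted p = 0.99), at a level of 13.54 in EtOH, near the highest value on the arrays, where little change can be measured. Pparg, the receptor that rosiglitazone binds, rose (0.24 ± 0.05, adjusted p = 0.0255), but not without EtOH 2 (adjusted p 0.108), EtOH 3 (0.0979), 4OHT 1 (0.0894), 4OHT 2 (0.0658) or 4OHT 3 (0.105). Shifts in other lists passed with the preset correlation only. The medians were positive in oxidative phosphorylation (0.08), tricarboxylic acid cycle (0.12), fatty acid oxidation (0.10), peroxisomal (0.15), p53 target (0.15), white-adipose-selective (0.08) and cholesterol genes (0.06). They were negative in extracellular matrix (-0.17), cytosolic ribosomal protein (-0.17), unfolded protein response (-0.05) and endothelial genes (-0.14). In these 11 lists the adjusted p with an estimated correlation lay between 0.0706 (p53 targets) and 0.570 (cholesterol and endothelial genes). Few of their members passed. Of the oxidative phosphorylation subunits 3 of 70 rose and 0 fell (3 and 0 adjusted over the list alone), of the p53 targets 4 of 22 rose and 0 fell (10 and 1 adjusted over the list alone), of the ribosomal proteins 0 of 31 rose and 5 fell (0 and 13 adjusted over the list alone) and of the unfolded protein response genes 0 of 19 rose and 3 fell (0 and 3 adjusted over the list alone). The first count was 1 without EtOH 2 or EtOH_Rosi 3 and 0 without EtOH 1, EtOH 3, 4OHT 1, 4OHT 2, 4OHT 3, EtOH_Rosi 2 or 4OHT_Rosi 2. The p53 target count was 2 without EtOH 1 or 4OHT 3 and 1 without EtOH 2, EtOH 3, 4OHT 1 or 4OHT 2. The ribosomal count was 1 without EtOH 2 or 4OHT 1, 0 without EtOH 3 or 4OHT 2, 3 without 4OHT 3 and 8 without 4OHT_Rosi 3. The unfolded protein response count was 1 without EtOH 2 or 4OHT 3 and 0 without EtOH 3, 4OHT 1 or 4OHT 2. The others were the tricarboxylic acid cycle (1 of 22 rose and 1 fell, or 8 and 1 adjusted over the list alone), fatty acid oxidation (2 of 22 rose and 0 fell, or 2 and 0 adjusted over the list alone), peroxisomal (2 of 22 rose and 0 fell, or 4 and 0 adjusted over the list alone) and white-adipose-selective genes (3 of 15 rose and 1 fell, or 3 and 1 adjusted over the list alone). Cholesterol (2 of 17 rose and 0 fell, or 4 and 0 adjusted over the list alone), extracellular matrix (0 of 29 rose and 2 fell, or 0 and 7 adjusted over the list alone) and endothelial genes (0 of 14 rose and 0 fell, or 0 and 1 adjusted over the list alone) completed them. The 2 fatty acid oxidation rises became 0 without EtOH 2, EtOH 3, 4OHT 1 or 4OHT 2 and 1 without 4OHT 3, EtOH_Rosi 1, EtOH_Rosi 2, 4OHT_Rosi 1 or 4OHT_Rosi 2. The 2 extracellular matrix falls became 1 without EtOH 1, 0 without EtOH 2, EtOH 3, 4OHT 1, 4OHT 2 or 4OHT 3 and 5 without 4OHT_Rosi 3. White-adipose-selective genes lost the preset call without EtOH 2, EtOH 3, 4OHT 1 or 4OHT 2 (adjusted p from 0.0556 to 0.0818), cholesterol genes without EtOH 2, EtOH 3 or 4OHT 1 (0.0778 to 0.126), and endothelial genes without EtOH 3 or 4OHT 3 (0.0628 and 0.108). Without EtOH 3 the medians were 0.048 for white-adipose-selective, 0.065 for fatty acid oxidation and -0.089 for endothelial genes, and without EtOH 1 that of oxidative phosphorylation was 0.131. The cholesterol median was 0.123, 0.025 or 0.093 without EtOH 1, 4OHT 1 or 4OHT 3, and the unfolded protein response median -0.085, -0.072 or -0.082 without EtOH 2, 4OHT 2 or 4OHT 3.

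In all, 472 genes were higher and 396 lower after 4-hydroxytamoxifen without rosiglitazone, and 54 and 16 of them changed at least 2-fold. Leaving out EtOH 2, EtOH 3, 4OHT 1 or 4OHT 2 gave 297, 276, 288 or 286 higher genes. For lower genes, leaving out EtOH 1, EtOH 2, EtOH 3, 4OHT 1, 4OHT 2 or 4OHT 3 gave 243, 202, 254, 211, 189 or 201. Estimated array weights, which gave EtOH 2 a weight of 2.66 and 4OHT_Rosi 3 a weight of 0.519, raised the counts to 1167 and 1077.

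With rosiglitazone, the same treatment again raised interferon-stimulated genes: 51 of 54 rose and 1 fell (52 and 1 adjusted over the list alone), with a median of 1.04 (adjusted p = 4.64e-68, and adjusted p = 0.0386 with an estimated correlation). Irf7 rose 4.69-fold (2.23 ± 0.14, adjusted p = 1.65e-06), Ifit1 by 2.63 ± 0.29 (adjusted p = 9.5e-05) and the nucleic acid sensor Zbp1 by 2.34 ± 0.17 (adjusted p = 4.93e-06). Other large rises were in Bpifa6 (2.85 ± 0.10, adjusted p = 1.12e-08), Oas1g (2.81), BC023105 (2.67) and Cmpk2 (2.24). In the MHC class I list 10 of 17 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.30 (adjusted p = 7.96e-13, and adjusted p = 0.0636 with an estimated correlation). They included Nlrc5, the transactivator of MHC class I genes (0.68 ± 0.07, adjusted p = 9.49e-05), and Tap1 (0.61). The pathway component list did not pass (2 of 26 rose and 0 fell, or 2 and 0 adjusted over the list alone, list adjusted p = 0.503), with Tlr3 at 0.69 ± 0.08 (adjusted p = 9.84e-05). Macrophage and leukocyte markers had a median of 0.14 (2 of 18 rose and 1 fell, or 2 and 2 adjusted over the list alone, list adjusted p = 0.164).

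Thermogenic genes were lower after 4-hydroxytamoxifen with rosiglitazone. None of the 30 rose and 8 fell (1 and 8 adjusted over the list alone). The median was -0.08 and the mean -0.27, since the falls were large and few. Ucp1 fell by 1.58 ± 0.14 (2.98-fold lower, adjusted p = 1.97e-05), and Cidea, a lipid droplet protein abundant in brown fat, by 1.56 ± 0.15 (adjusted p = 4.15e-05). The cytochrome c oxidase subunits Cox8b (-1.33 ± 0.14, adjusted p = 9.08e-05) and Cox7a1 (-0.79 ± 0.12, adjusted p = 0.00135) fell as well, while the coactivator Ppargc1a differed by -0.03 ± 0.13 (adjusted p = 0.932). The list passed with the preset correlation (adjusted p = 0.000106) but not with an estimated correlation (adjusted p = 0.192), and 5 genes fell without EtOH_Rosi 2 or EtOH_Rosi 3, the second with a median of -0.05. General adipocyte genes went both ways: 3 of 33 rose and 2 fell (4 and 2 adjusted over the list alone), median 0.06, list adjusted p = 0.0785. The 3 rises became 1 without EtOH_Rosi 3 or 4OHT_Rosi 3, and the 2 falls 0 without EtOH_Rosi 1 or EtOH_Rosi 2 and 1 without 4OHT 2, EtOH_Rosi 3, 4OHT_Rosi 1, 4OHT_Rosi 2 or 4OHT_Rosi 3. Adipoq differed by 0.08 ± 0.06 (adjusted p = 0.51), Fabp4 by -0.04 ± 0.05 (adjusted p = 0.763) and Pparg by 0.06 ± 0.05 (adjusted p = 0.598). The other large falls were in the integrin subunit Itgad (-1.76 ± 0.10, adjusted p = 1.14e-06), Itpka (-1.36) and Muc2 (-1.25).

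**Figure D2:**
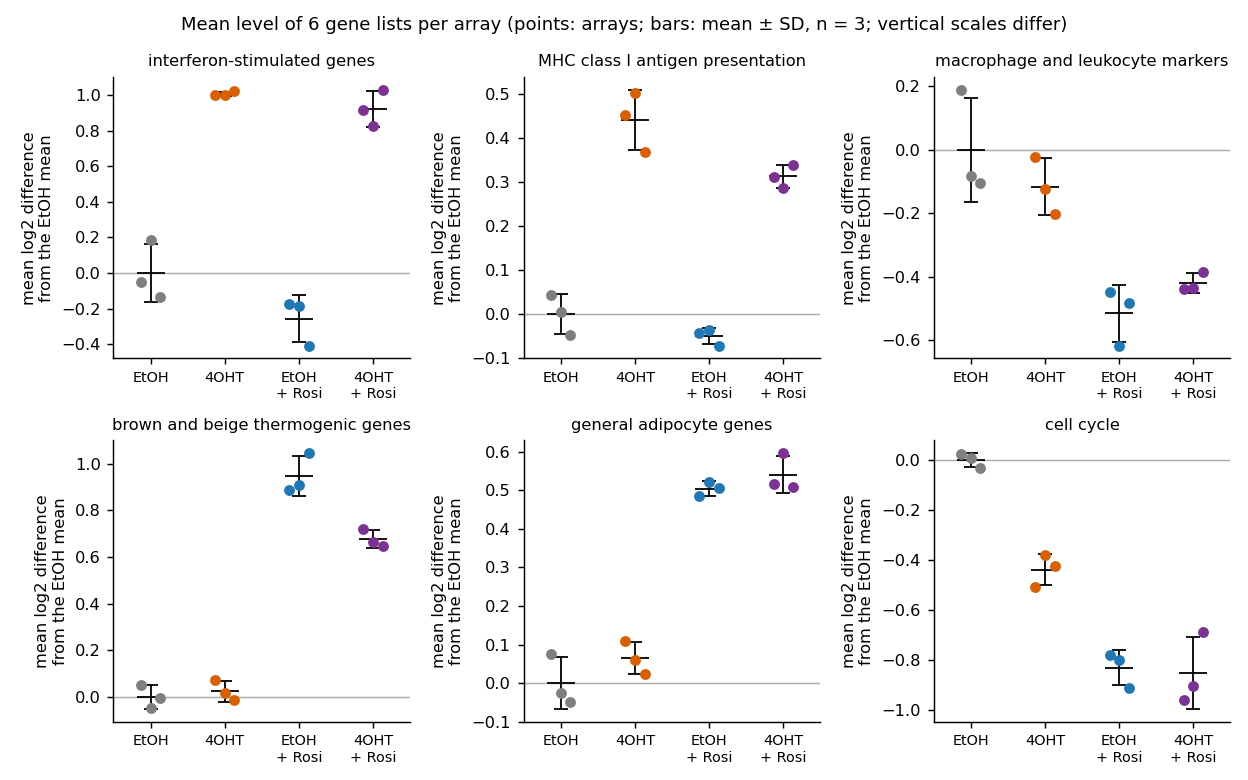
Mean log2 difference of each array from the EtOH mean (vertical axes, which differ between panels) over the measured genes of 6 fixed lists in the 4 groups. Points are arrays, and bars give the mean and SD of 3 arrays. Interferon-stimulated genes averaged 1.01 ± 0.01 in 4OHT and 0.92 ± 0.10 in 4OHT_Rosi, and thermogenic genes 0.95 ± 0.08 in EtOH_Rosi and 0.68 ± 0.04 in 4OHT_Rosi.

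Smooth muscle and myofibroblast genes, which encode contractile proteins, were higher in this comparison: 7 of 16 rose and 1 fell (12 and 1 adjusted over the list alone), median 0.41 (adjusted p = 1e-07, and adjusted p = 0.168 with an estimated correlation). The smooth muscle myosin gene Myh11 rose by 0.53 ± 0.08 (adjusted p = 0.00106) and Ldb3 by 0.43 ± 0.06 (adjusted p = 0.000667). The 7 rises became 4 without EtOH 2, 4OHT 1, 4OHT 2, 4OHT 3 or EtOH_Rosi 3 and 3 without 4OHT_Rosi 3, the array that stood apart on the third component, and without it the median was 0.262. Of the inflammatory genes 8 of 25 rose and none fell, adjusted over the list alone too, with a median of 0.10 (adjusted p = 0.00269, and adjusted p = 0.44 with an estimated correlation). Without EtOH_Rosi 3, 5 rose and the median was 0.053, and without 4OHT_Rosi 3 the median was 0.048. Among them were the chemokine genes Ccl2 (1.09 ± 0.18, adjusted p = 0.00184) and Cxcl1 (0.55 ± 0.10, adjusted p = 0.0036). Glycolysis and hypoxia genes were lower (1 of 22 rose and 8 fell, or 1 and 16 adjusted over the list alone, median -0.24, adjusted p = 1.36e-08, and adjusted p = 0.173 with an estimated correlation). The hypoxia-responsive gene Ndrg1 (-0.92 ± 0.10, adjusted p = 6.88e-05) and Slc2a1 (-0.39 ± 0.05, adjusted p = 0.000696) were among them. The 8 falls became 4 without EtOH_Rosi 2, EtOH_Rosi 3 or 4OHT_Rosi 3 and 5 without 4OHT_Rosi 2.

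Of the p53 target list 5 of 22 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.000238, and adjusted p = 0.151 with an estimated correlation). Eda2r rose by 0.64 ± 0.11 (adjusted p = 0.0027), while Btg2 fell by 0.44 ± 0.07 (adjusted p = 0.00196). Without EtOH_Rosi 2, EtOH_Rosi 3 or 4OHT_Rosi 3, 3, 3 or 1 of its genes rose. Epithelial markers had a median of 0.28 with 1 of 11 called, the tight junction gene Cldn4 (0.54 ± 0.10, adjusted p = 0.00647), and 6 called adjusted over the list alone. Without EtOH 1 or EtOH_Rosi 1, 2 were called, and without 4OHT_Rosi 2, 3. That list passed with the preset correlation (adjusted p = 0.00155), but adjusted p = 0.273 with an estimated correlation. Cell cycle genes, lower without rosiglitazone, had a median of 0.007 here that turned negative under quantile normalization, and a mean of -0.02, with 1 fall of 28 and 0 adjusted over the list alone (list adjusted p = 0.855). Oxidative phosphorylation (-0.09), fatty acid oxidation (-0.09), tricarboxylic acid cycle (-0.08) and white-adipose-selective genes (0.15) shifted by the medians given: in turn, 0 of 70 rose and 2 fell (0 and 2 adjusted over the list alone), 2 of 22 rose and 2 fell (2 and 5 adjusted over the list alone), 0 of 22 rose and 3 fell (0 and 4 adjusted over the list alone) and 5 of 15 rose and 2 fell (6 and 2 adjusted over the list alone). The 2 falls of oxidative phosphorylation became 0 without EtOH_Rosi 2 or EtOH_Rosi 3, 1 without 4OHT_Rosi 3, 4 without 4OHT_Rosi 2, 5 without 4OHT 3 and 7 without EtOH_Rosi 1. The 2 falls of fatty acid oxidation became 0 without 4OHT 1, 4OHT 2, 4OHT 3, EtOH_Rosi 2, EtOH_Rosi 3 or 4OHT_Rosi 3 and 1 without EtOH 1, EtOH 2, EtOH 3, 4OHT_Rosi 1 or 4OHT_Rosi 2. The 3 falls of the tricarboxylic acid cycle became 5 without EtOH_Rosi 1 and 1 without EtOH_Rosi 3 or 4OHT_Rosi 3, and the 5 white-adipose rises became 3 without EtOH_Rosi 1, EtOH_Rosi 3 or 4OHT_Rosi 1. Their adjusted p was 4.14e-05, 0.0115, 0.00999 and 0.0142 with the preset correlation, but adjusted p = 0.637, 0.76, 0.76 and 0.151 with an estimated correlation. Fatty acid oxidation (0.0913 without EtOH_Rosi 3) and tricarboxylic acid cycle genes (0.114 without EtOH_Rosi 3, where the median was -0.048, and 0.151 without 4OHT_Rosi 3) also lost the preset call. No other list passed in this comparison.

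In all, 1032 genes were higher and 750 lower, and 73 and 19 of them changed at least 2-fold. Without EtOH_Rosi 2 the count of lower genes was 452, and a fit of these 2 groups alone called 499 and 330. Without and with rosiglitazone, the 4-hydroxytamoxifen effects correlated across all 22180 genes with a Pearson r of 0.433 and a Spearman rho of 0.213. Genes are not independent replicates. The 2 comparisons share no array, but no label says whether cells with and without rosiglitazone were pretreated separately. A shared pretreatment could therefore act in both. There were 257 genes higher in both, where independent lists would share 21.96, and 98 lower in both, where they would share 13.39. Both comparisons used the same variance estimate of each gene, so the numbers for independent lists are only a rough guide. The calls went in opposite directions for 10 genes. The 98 became 56, 45, 41 or 49 without EtOH 1, EtOH 2, 4OHT 2 or 4OHT 3, and 155 without 4OHT_Rosi 3.

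**Figure D3:**
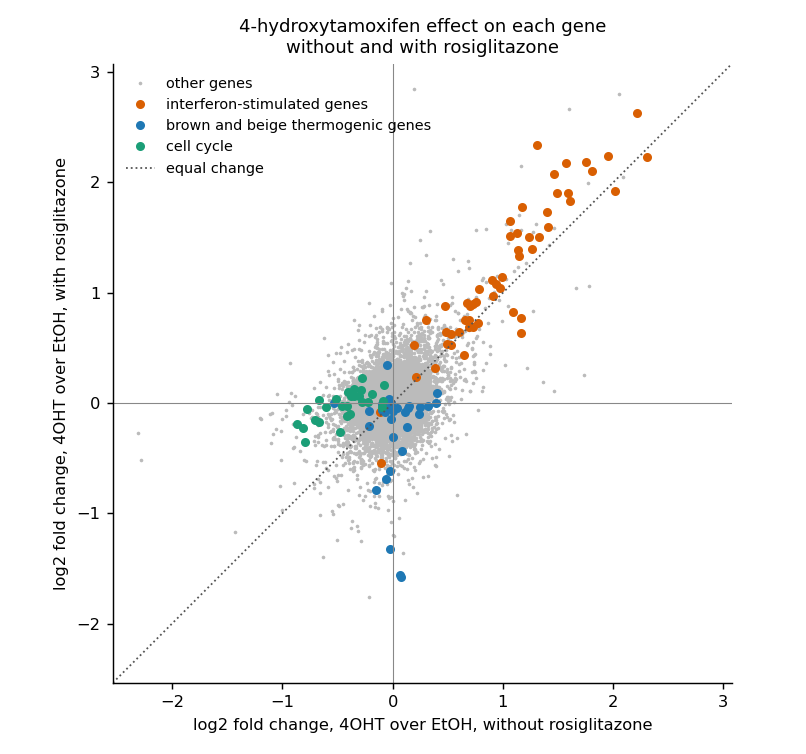
Log2 fold change after 4-hydroxytamoxifen without rosiglitazone (horizontal axis) against that with rosiglitazone (vertical axis) for the 22180 genes. Each point is a gene, 3 fixed lists are coloured, and the dotted line marks equal change. The interferon-stimulated genes, with medians of 0.98 and 1.04, lie along the line, Ucp1 and Cidea lie near 0 on the horizontal axis and below -1.5 on the vertical, and most cell cycle genes lie left of 0 and near 0 on the vertical.

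The interaction tested whether the 4-hydroxytamoxifen effect differed between the conditions. Thermogenic genes stood out: Ucp1 (-1.65 ± 0.19, adjusted p = 0.00591), Cidea (-1.63 ± 0.21, adjusted p = 0.00726) and Cox8b (-1.30 ± 0.20, adjusted p = 0.0122) had lower effects with rosiglitazone. Without rosiglitazone Ucp1 and Cidea were dim, at most 5.86 and 5.07 on any array, so a fall there may have been hard to measure. Their interaction does not tell an effect that needs rosiglitazone from a fall hidden by low signal. In the list 4 of 30 were called lower and none higher (7 and 1 adjusted over the list alone), with a median of -0.19 (adjusted p = 3.1e-05, and adjusted p = 0.375 with an estimated correlation). Bpifa6 (2.66 ± 0.14, adjusted p = 2.25e-06), Ngfr (1.77 ± 0.23, adjusted p = 0.00726), Mtarc1 (1.23 ± 0.11, adjusted p = 0.000514) and Sfrp4 (1.07 ± 0.15, adjusted p = 0.00779) had higher effects with it. Itgad (-1.55 ± 0.15, adjusted p = 0.00074) and the acute phase gene Orm3 (-1.49 ± 0.23, adjusted p = 0.0125) had lower ones. Rosiglitazone also raised Cox8b and Itgad after ethanol, and whether low signal without it hid a fall in them was not tested. Irf7 differed by -0.08 ± 0.20 (adjusted p = 0.916) and Ifit1 by 0.42 ± 0.41 (adjusted p = 0.726). The median of the interferon-stimulated list, 0.17, passed with the preset correlation (adjusted p = 0.000489), but adjusted p = 0.609 with an estimated correlation. Without EtOH 2 the median was 0.076 and the adjusted p 0.108, and without EtOH_Rosi 3 the median was 0.105.

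The cell cycle list had a median difference of 0.44, with 6 of 28 genes called (22 adjusted over the list alone). Without EtOH 3, 3 were called, without 4OHT 2 or EtOH_Rosi 3, 2, and without EtOH_Rosi 2 or 4OHT_Rosi 3, 1. Leaving out EtOH 1, EtOH 2, 4OHT 1 or 4OHT 3 left 0 called. Its adjusted p was 1.18e-19 with the preset correlation, and adjusted p = 0.375 with an estimated correlation. Oxidative phosphorylation (-0.19), tricarboxylic acid cycle (-0.21) and fatty acid oxidation genes (-0.20) had lower effects with rosiglitazone, with 1, 0 and 0 genes called (14, 9 and 6 adjusted over the list alone), each list at adjusted p = 0.375 with an estimated correlation. Of the 29 lists, 16 passed with the preset correlation and none with an estimated correlation. In all, 116 genes had a higher effect and 107 a lower effect with rosiglitazone. Leaving out EtOH 1, EtOH 2, EtOH 3, 4OHT 1, 4OHT 2 or 4OHT 3 gave 36, 35, 49, 24, 32 or 47 higher and 54, 33, 40, 27, 37 or 44 lower. Leaving out EtOH_Rosi 2, EtOH_Rosi 3 or 4OHT_Rosi 3 gave 32, 49 or 43 higher and 36, 64 or 50 lower. Without 4OHT_Rosi 1 there were 177 higher genes, and without EtOH_Rosi 1 there were 173 lower genes.

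Rosiglitazone itself, compared after ethanol, shifted thermogenic, oxidative phosphorylation, fatty acid oxidation and general adipocyte genes up and progenitor, extracellular matrix, smooth muscle and cell cycle genes down. Of the 29 lists, 20 passed with the preset correlation, and none with an estimated correlation, where the smallest adjusted p = 0.0874. In the thermogenic list 16 of 30 rose and 2 fell (17 and 3 adjusted over the list alone), with a median of 0.39. The fatty acid elongase Elovl3 rose 28.2-fold (4.82 ± 0.16, adjusted p = 5.54e-10), Cox8b by 3.28 ± 0.14 (adjusted p = 5.48e-09) and Ucp1 by 2.14 ± 0.14 (adjusted p = 1.19e-07). Of the oxidative phosphorylation subunits 65 of 70 rose and 0 fell (65 and 0 adjusted over the list alone), with a median of 0.57. The mitochondrially encoded genes had a median level of 13.37, near the highest value of any probe set (13.91), where a rise can hardly be measured, so their median change of 0.02 (list adjusted p = 0.748) decides nothing. Positive medians were also found for fatty acid oxidation (20 of 22 rose and 0 fell, or 20 and 0 adjusted over the list alone, median 0.88), the tricarboxylic acid cycle (21 of 22 rose and 1 fell, or 21 and 1 adjusted over the list alone, median 0.68) and peroxisomal genes (19 of 22 rose and 0 fell, or 19 and 0 adjusted over the list alone, median 0.61). Slc25a20, the mitochondrial carnitine carrier, rose by 1.57 ± 0.06 (adjusted p = 6.59e-10) and the peroxisomal thiolase Acaa1b by 2.74 ± 0.10 (adjusted p = 9.62e-10). General adipocyte genes were higher too (26 of 33 rose and 3 fell, or 26 and 3 adjusted over the list alone, median 0.45), with the lipid droplet gene Cidec at 1.89 ± 0.07 (adjusted p = 1.47e-09). Smaller positive medians were found for cholesterol genes (9 of 17 rose and 1 fell, or 9 and 1 adjusted over the list alone, median 0.25) and glycolysis and hypoxia genes (17 of 22 rose and 3 fell, or 17 and 3 adjusted over the list alone, median 0.35). The largest rises were in Sptlc3, a serine palmitoyltransferase subunit (5.54 ± 0.12, adjusted p = 1.59e-11), Elovl3, Itgad (4.16), Gys2 (3.99), Car4 (3.79) and Aadac (3.78).

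The gene for leptin, Lep, had the largest fall with rosiglitazone (-3.57 ± 0.18, adjusted p = 2.29e-08), followed by Cyp2f2 (-3.33), Chl1 (-3.04), Prnd (-2.96), Reg1 (-2.70) and H2-M9 (-2.42). Progenitor and fibroblast genes fell together (0 of 22 rose and 16 fell, or 1 and 16 adjusted over the list alone, median -0.95), with the receptor Pdgfra at -1.24 ± 0.09 (adjusted p = 3.6e-07). Extracellular matrix (0 of 29 rose and 26 fell, or 0 and 26 adjusted over the list alone, median -0.72), smooth muscle (1 of 16 rose and 15 fell, or 1 and 15 adjusted over the list alone, median -0.83) and cell cycle genes (0 of 28 rose and 27 fell, or 0 and 27 adjusted over the list alone, median -0.84) were also lower. Top2a, the topoisomerase of dividing cells, fell by 1.24 ± 0.07 (adjusted p = 6.59e-08). Inflammatory genes (1 of 25 rose and 16 fell, or 1 and 16 adjusted over the list alone, median -0.34), leukocyte markers (0 of 18 rose and 14 fell, or 0 and 16 adjusted over the list alone, median -0.54) and endothelial markers (0 of 14 rose and 13 fell, or 0 and 13 adjusted over the list alone, median -0.68) were lower. Interferon-stimulated genes had a median of -0.27, and 3 of 54 rose and 19 fell (3 and 20 adjusted over the list alone), with 12 falls and a median of -0.129 without EtOH 2 and a median of -0.173 without EtOH_Rosi 3. Pathway components (-0.10), ribosomal proteins (-0.30), unfolded protein response genes (-0.21) and estrogen receptor targets (-0.12) had negative medians and passed with the preset correlation: in turn, 1 of 26 rose and 12 fell (4 and 12 adjusted over the list alone), 0 of 31 rose and 19 fell (0 and 21 adjusted over the list alone), 2 of 19 rose and 12 fell (3 and 14 adjusted over the list alone) and 1 of 12 rose and 5 fell (1 and 6 adjusted over the list alone). Without EtOH_Rosi 3, 7 unfolded protein response genes fell. In a limma fry test, which asks whether a list's genes move one way and not whether they move more than others, the thermogenic list had an adjusted p of 9.58e-07. In all 3190 genes were higher and 3623 lower, or 30.7% of those tested.

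After 4-hydroxytamoxifen, rosiglitazone changed 2573 genes upward and 2693 downward. Across all genes its effect correlated with that after ethanol at a Pearson r of 0.842 and a Spearman rho of 0.690, and the 2 comparisons share no array. There were 2031 genes higher in both, where independent lists would share 370.1, and 2152 lower in both, where they would share 439.9, with 19 in opposite directions. Here too both comparisons used the same variance estimate of each gene, so the numbers for independent lists are only a rough guide. Elovl3 rose by 4.51 ± 0.16 (adjusted p = 1.47e-09), Sptlc3 by 5.02 ± 0.12 (adjusted p = 5.71e-11) and Cidec by 2.19 ± 0.07 (adjusted p = 7.98e-10). Bpifa6 (3.68), Gys2 (3.96) and Aadac (3.54) rose as well. Lep fell by 3.37 ± 0.18 (adjusted p = 4.55e-08), and the acute phase genes Orm3 (-2.42), Orm2 (-2.39) and Saa2 (-2.43) were among the 6 largest falls. In the thermogenic list 13 of 30 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.16. Ucp1 rose by 0.48 ± 0.14 (adjusted p = 0.02), a call that ended without 4OHT 1 (adjusted p 0.0775), 4OHT 3 (0.0616), 4OHT_Rosi 1 (0.0718) or 4OHT_Rosi 3 (0.0509). Cidea differed by 0.18 ± 0.15 (adjusted p = 0.461), and Ppargc1a rose by 1.55 ± 0.13 (adjusted p = 1.63e-06).

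The other lists after 4-hydroxytamoxifen kept the signs they had after ethanol in most cases. Of the oxidative phosphorylation subunits 54 of 70 rose and 0 fell (61 and 0 adjusted over the list alone), with a median of 0.36, and in fatty acid oxidation 21 of 22 rose and 0 fell (21 and 0 adjusted over the list alone), median 0.72. General adipocyte genes had a median of 0.37 (22 of 33 rose and 3 fell, or 24 and 3 adjusted over the list alone), and de novo lipogenesis genes one of 0.16 (6 of 16 rose and 2 fell, or 7 and 2 adjusted over the list alone). Progenitor (1 of 22 rose and 14 fell, or 1 and 14 adjusted over the list alone, median -0.67), smooth muscle (1 of 16 rose and 13 fell, or 1 and 13 adjusted over the list alone, median -0.44) and cell cycle genes (0 of 28 rose and 20 fell, or 0 and 22 adjusted over the list alone, median -0.42) were lower. Extracellular matrix genes (1 of 29 rose and 23 fell, or 2 and 24 adjusted over the list alone, median -0.47) had 15, 13, 12 or 13 falls without 4OHT 1, 4OHT 3, 4OHT_Rosi 1 or 4OHT_Rosi 2. Interferon-stimulated genes had a median of -0.07 (2 of 54 rose and 7 fell, or 2 and 7 adjusted over the list alone, list adjusted p = 0.278), with 3 falls without 4OHT_Rosi 1. MHC class I genes (median -0.11, adjusted p = 0.0429, and adjusted p = 0.399 with an estimated correlation) had 2 rises and 4 falls of 17 (2 and 5 adjusted over the list alone) and lost the call without 4OHT 1 (0.0713), 4OHT 2 (0.0988), 4OHT_Rosi 2 (0.0762) or 4OHT_Rosi 3 (0.0523). Of the 29 lists, 20 passed with the preset correlation and none with an estimated correlation, where the smallest adjusted p = 0.113. The lymphocyte, skeletal muscle and Schwann cell lists passed in none of the 5 comparisons, with medians after 4-hydroxytamoxifen with rosiglitazone of -0.03, 0.02 and 0.03. Nor did the mitochondrially encoded list (median -0.04 in that comparison), whose signal near the top of the range limits what it can show. Median, mean and test direction differed in sign only in lists that did not pass. An example was the rosiglitazone effect on estrogen receptor targets in cells given 4-hydroxytamoxifen (median 0.005, mean -0.24, list adjusted p = 0.0792).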

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

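The tests of leukocyte content, of the drug or Cre, of adipocyte number and of both cell cycle explanations, and the count of splits by intact labels, were chosen only after the result was seen, and those of a uniformly weaker rosiglitazone response and of other splits of the arrays were set beforehand. The results in this part stood out because the limma interaction test found the 4-hydroxytamoxifen effect to differ with and without rosiglitazone. Each value is the effect with rosiglitazone minus the effect without. Of 29 named genes, 11 kept the call without any 1 array: Bpifa6 (2.66), Ngfr (1.77), Mtarc1 (1.23), Sfrp4 (1.07), Mmp12 (1.02), Sncg (-0.74), Cox8b (-1.30), Orm3 (-1.49), Itgad (-1.55), Cidea (-1.63) and Ucp1 (-1.65). Aplnr (1.22) and Mest (0.57) lost it without 4OHT 1, at an adjusted p of 0.0513 and 0.0566. Plk1 (0.73) lost it without EtOH 1, EtOH 2, 4OHT 1, 4OHT 3 or EtOH_Rosi 2, with an adjusted p of up to 0.0628, and Timp4 (-1.42) without EtOH 2, EtOH 3, 4OHT 1, 4OHT 2 or EtOH_Rosi 2, with up to 0.0787. Top2a (0.57) lost it without EtOH 1, EtOH 2, 4OHT 1, 4OHT 3, EtOH_Rosi 2 or 4OHT_Rosi 3, with up to 0.0772. The other 13 lost it without any of 8 to 11 of the arrays: Shisa6 (1.11), Pgr (0.71), Kdr (0.61), Cd53 (0.59), Ube2c (0.55), Mcm3 (0.50), Thbs2 (0.45), Ndufs8 (-0.42), Isg20 (-0.44), Npr3 (-0.46), Sirt3 (-0.52), Muc2 (-0.97) and Itpka (-1.46). Their highest adjusted p lay between 0.083 (Itpka) and 0.127 (Cd53 and Mcm3). They passed only without the arrays named here: 4OHT_Rosi 1 for Kdr, EtOH_Rosi 1 or 4OHT_Rosi 1 for Shisa6, Cd53 and Ube2c, EtOH 3 or 4OHT_Rosi 1 for Mcm3, 4OHT 3 or 4OHT_Rosi 1 for Isg20, and EtOH 1 or EtOH_Rosi 1 for Ndufs8. For Npr3 these were EtOH 1, EtOH_Rosi 1 or 4OHT_Rosi 1, for Sirt3 EtOH 1, EtOH_Rosi 1 or 4OHT_Rosi 2, for Pgr 4OHT 2, EtOH_Rosi 1 or 4OHT_Rosi 1, and for Muc2 EtOH_Rosi 1, 4OHT_Rosi 1 or 4OHT_Rosi 3. For Thbs2 they were 4OHT 3, EtOH_Rosi 1, 4OHT_Rosi 1 or 4OHT_Rosi 2, and for Itpka EtOH_Rosi 1, EtOH_Rosi 3, 4OHT_Rosi 1 or 4OHT_Rosi 2.

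Of the lists, 16 differed by camera with the preset correlation and none with an estimated correlation, where the smallest adjusted p = 0.375. The median differences were 0.44 for cell cycle, 0.35 for smooth muscle, 0.32 for epithelial, 0.25 for extracellular matrix, 0.19 for leukocyte, 0.17 for interferon-stimulated, 0.16 for progenitor, 0.12 for endothelial, 0.12 for ribosomal protein, 0.11 for unfolded protein response and 0.093 for inflammatory genes. They were -0.083 for peroxisomal, -0.19 for thermogenic, -0.19 for oxidative phosphorylation, -0.20 for fatty acid oxidation and -0.21 for tricarboxylic acid cycle genes. The call ended without EtOH 2 for interferon-stimulated genes (median 0.076, adjusted p 0.108), whose median was 0.105 without EtOH_Rosi 3. It ended without EtOH_Rosi 3 or 4OHT_Rosi 3 for progenitor (0.0518 and 0.0761) and unfolded protein response genes (0.0518 and 0.144), and without 4OHT 3, 4OHT_Rosi 2 or 4OHT_Rosi 3 for endothelial genes (0.0586, 0.0716 and 0.0556). For peroxisomal genes it ended without EtOH 2, EtOH 3, 4OHT 1, EtOH_Rosi 2, EtOH_Rosi 3 or 4OHT_Rosi 3 (0.0748, 0.292, 0.102, 0.0948, 0.0878 and 0.112). Medians moved by over 1.5 times for inflammatory (0.162 without EtOH_Rosi 1, 0.217 without 4OHT_Rosi 1 and 0.062 without 4OHT_Rosi 3), endothelial (0.242 without 4OHT_Rosi 1 and 0.067 without 4OHT_Rosi 3) and extracellular matrix genes (0.152 without EtOH_Rosi 3 and 0.162 without 4OHT_Rosi 3). So did those of epithelial (0.17) and unfolded protein response genes (0.05) without 4OHT_Rosi 3, leukocyte markers without EtOH 1 (0.095) and peroxisomal genes without EtOH 3 (-0.048).

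The first pattern weighed was the rise of interferon-stimulated genes after 4-hydroxytamoxifen. More leukocytes in those cultures would raise their markers by about as much as the interferon-stimulated genes (medians 0.98 without and 1.04 with rosiglitazone), but the 18 markers averaged -0.116 ± 0.0611 (SE over markers) and 0.0957 ± 0.0675. Of the most abundant markers, Lyz2 (mean level 11.59) changed by -0.24 and -0.20 and Cd68 (11.12) by 0.03 and 0.16, which argues against it, and none of the markers was in another list. The drug or Cre activity itself could raise these genes without any part of Prdm16, and cannot be told apart from loss of Prdm16 here. The number of arrays of cells without floxed Prdm16 was 0.

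The second was the fall of thermogenic genes under rosiglitazone. Fewer or less mature adipocytes would lower general adipocyte genes too, but the 26 of them that rosiglitazone raised changed by 0.0233 ± 0.0326 (SE over genes), against -0.483 ± 0.141 for the 16 thermogenic genes it raised. Equal falls need not follow, since the whole adipocyte list averaged 0.50 above EtOH in EtOH_Rosi and the whole thermogenic list 0.95. Smooth muscle genes, which rosiglitazone lowered, were higher after 4-hydroxytamoxifen with rosiglitazone, as less mature cells would have it (median 0.41, or 0.262 without 4OHT_Rosi 3, list adjusted p = 1e-07, and adjusted p = 0.168 with an estimated correlation). Progenitor genes did not pass: 5 rose and 3 fell, with a mean of 0.15 (list adjusted p = 0.0653). Relative to EtOH they averaged -0.50 in 4OHT_Rosi 3, against -0.76 and -0.70 in 4OHT_Rosi 1 and 4OHT_Rosi 2, so the mean leans on 1 array. Of other lists that rosiglitazone lowered, extracellular matrix (0.04), endothelial (0.008) and cell cycle genes (0.007) had medians near 0. Inflammatory (0.10) and leukocyte genes (0.14) had larger ones. Less mature cells therefore stay open for the smooth muscle genes, while the adipocyte genes argue against them as the whole cause of the thermogenic fall. A rosiglitazone response weaker by 1 factor for every gene was tested on the fraction of the rise kept after 4-hydroxytamoxifen. The thermogenic genes kept a median of 0.634, at percentile 0.5 of 10000 random sets of raised genes of like size, whose median was 0.809 and 5th percentile 0.687. Over all 3190 raised genes, not matched on the size of the rise, the median fraction kept was 0.699, closer to that of the thermogenic genes. Genes of the random sets were drawn singly and need not vary together between arrays, as thermogenic genes may. The percentile can therefore overstate the difference and does not decide whether 1 factor held for every gene. The drug or Cre stays open here as well.

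The third was the fall of cell cycle genes seen without rosiglitazone but not with it. Rosiglitazone lowered cell cycle genes after ethanol (27 fell, median -0.84). Whether this accounts for the absence of a further fall after 4-hydroxytamoxifen stays open. Their mean level in EtOH_Rosi minus that in 4OHT was -0.394 ± 0.0545 (SE over arrays), which restates the larger fall with rosiglitazone. All groups were measured after both treatments, so the arrays do not show an order of the changes. Cells further along in differentiation could not be told from other causes, since progenitor genes changed by -0.0203 ± 0.0704 (SE over genes) and general adipocyte genes by 0.0648 ± 0.035. The 4-hydroxytamoxifen effect on proliferation through the drug itself was not tested.

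Other splits of the arrays were set against the counts of called genes. For each comparison of 2 groups, the real split was 1 of 10, too few for a share under 0.05. The real count and the highest of the other splits were 868 and 0 for 4-hydroxytamoxifen without rosiglitazone, 1782 and 3 with it, 6813 and 0 for rosiglitazone after ethanol, and 5266 and 0 after 4-hydroxytamoxifen. For the interaction, 3 of 100 splits of the 4-hydroxytamoxifen labels within each rosiglitazone condition gave at least the real 223 genes, the real one included, and the highest other had 258. These splits do not settle whether chance could give such a count. A split that mixes treated and ethanol arrays puts the 4-hydroxytamoxifen effect into the residual variance, and the 82 splits that mixed both conditions called at most 0 genes. Of the 11 others that left the labels of the rosiglitazone arrays intact, 2 gave at least 223. Their contrast still holds the real 4-hydroxytamoxifen effect with rosiglitazone, so this is not a rate that chance alone would give.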

How the results depend on the processing

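The counts of list members and of neighbours of Prdm16 without each array were chosen only after the result was seen, and the other alternatives were set beforehand. None of the values counted in this paragraph changed direction. Apart from them, the medians of 12 list results, none of them called, changed sign under quantile normalization or median centring. Only lists called in the main fit were counted, so none could newly pass. Of 1939 values for lists, 1782 kept direction and side of the threshold and 157 no longer passed. Only 3 of 85 list results kept both under every alternative. Of 13797 values for named genes, 12949 were counted as kept, 610 no longer passed and 238 newly passed. Under every alternative, 484 of 667 named gene results were kept. Of 509 values for the counts and results that answer a comparison, 436 kept theirs. Of 424 calls of named genes, 92 ended without some array.

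The values showed no pairing by replicate number: after group means were removed, 18 same-number pairs correlated at -0.053 on average and 36 different-number pairs at 0.026, and 0 of 12 arrays correlated best with its own number. The averages are tied to each other, since deviations within a group add up to 0. They do not settle whether arrays of the same number came from the same culture. With the replicate block, the fit gave 387 higher and 296 lower genes for 4-hydroxytamoxifen without rosiglitazone and 807 and 575 with it. Rosiglitazone gave 2984 and 3450 after ethanol and 2328 and 2437 after 4-hydroxytamoxifen, and the interaction 59 and 57.

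With only the 2 groups compared, counts were 499 higher and 330 lower for 4-hydroxytamoxifen with rosiglitazone, 622 lower without it, and 64 lower in both. With array weights, they were 1167 higher and 1077 lower without rosiglitazone, 198 and 198 for the interaction, and 175 lower in both. With an intensity trend and robust eBayes, they were 192 and 201 for the interaction and 156 lower in both. For genes above the 50th percentile, they were 200 and 181 for the interaction and 162 lower in both, and with all probe sets 17 and 23 for the interaction. The percentile filter and the use of all probe sets also change the number of tests adjusted for. The cause of these changes was not tested. A 2-fold minimum, which removes smaller changes by construction, left 54 higher and 16 lower for 4-hydroxytamoxifen without rosiglitazone, 73 and 19 with it, 240 and 315 for rosiglitazone after ethanol, 179 and 128 after 4-hydroxytamoxifen, and 12 and 12 for the interaction.

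With an estimated correlation, camera called 2 lists for 4-hydroxytamoxifen without rosiglitazone and 1 with it, and 0 for rosiglitazone after ethanol, 0 after 4-hydroxytamoxifen and 0 for the interaction. With the preset correlation the counts were 17, 12, 20, 20 and 16. An estimated correlation changes both the error and the degrees of freedom of the test, and these were not separated. It was below the preset 0.01 for white-adipose-selective genes, which still no longer passed. Fry, which tests a list without setting it against other genes, called 8 lists for 4-hydroxytamoxifen without rosiglitazone and 9 with it, 23 for rosiglitazone after ethanol, 22 after 4-hydroxytamoxifen and 0 for the interaction. An estimated correlation cannot move a median, but with it thermogenic genes (-0.077 after 4-hydroxytamoxifen with rosiglitazone and 0.39 after rosiglitazone) no longer passed, at adjusted p = 0.192 and adjusted p = 0.0874, while both passed with fry (0.00642 and 9.58e-07).

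Leaving out 1 array at a time gave 276 to 522 higher and 189 to 537 lower genes for 4-hydroxytamoxifen without rosiglitazone. It gave 452 to 739 lower with it, 24 to 177 higher and 27 to 173 lower for the interaction, and 41 to 155 lower in both. The Prdm16 interaction ranged from -0.65 to -0.475, and its adjusted p from 0.0458 without EtOH_Rosi 1 to 0.216 without EtOH 2. The cause was not tested. The fit of only 2 groups was not run for the interaction, which needs all 4, and genes below a percentile filter have no value under it. Array signal can limit dim genes, such as Prdm16 in its second probe set or Ucp1 and Cidea without rosiglitazone, and the brightest, such as the mitochondrially encoded genes.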

Other observations

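The families of genes in this part were picked out only after the result was seen, in a scan of 269 families that share a name stem, as was leaving out arrays for the genes beside Prdm16, while the test of those genes itself was set beforehand. None of the families passed camera with an estimated correlation. Guanylate-binding proteins, interferon-induced GTPases, rose together: 6 of 6 after 4-hydroxytamoxifen without rosiglitazone (median 1.10) and 6 of 6 with it (median 1.48). Gbp7 rose by 1.03 ± 0.11 (adjusted p = 0.000206) and 1.63 ± 0.11 (adjusted p = 3.73e-06). With an estimated correlation the family had adjusted p = 0.247 and adjusted p = 0.269.

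Chemokine genes of the Ccl family, which draw leukocytes, fell with rosiglitazone after ethanol in 8 of 11 (median -1.11), and 7 rose and 1 fell after 4-hydroxytamoxifen with rosiglitazone (median 0.48). With an estimated correlation these had adjusted p = 0.361 and adjusted p = 0.872. Macrophage and leukocyte markers also fell with rosiglitazone after ethanol (0 of 18 rose and 14 fell, or 0 and 16 adjusted over the list alone, median -0.54, adjusted p = 0.16 with an estimated correlation), and the family's fall was not set apart from theirs. The eotaxin gene Ccl11 fell by 1.80 ± 0.15 (adjusted p = 1.25e-06) with rosiglitazone after ethanol and rose by 1.34 ± 0.15 (adjusted p = 0.000136) after 4-hydroxytamoxifen with it. The interaction was called for 4 of the 11, and for 1 without EtOH 1, EtOH 2, EtOH 3, 4OHT 1, 4OHT 2, 4OHT 3 or EtOH_Rosi 2 and 2 without EtOH_Rosi 3 or 4OHT_Rosi 3.

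Carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, fell in 4 of 6 after 4-hydroxytamoxifen with rosiglitazone (median -0.33, adjusted p = 0.872 with an estimated correlation). Car2 fell by 0.70 ± 0.08 (adjusted p = 0.000201), and its interaction was -0.84 ± 0.12 (adjusted p = 0.00779).

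An effect of the excision on neighbouring genes was tested with the 20 tested genes nearest to Prdm16 in gene order. Without rosiglitazone 1 of 20 was called (Prxl2b, 0.33, adjusted p = 0.0494) and with it 1 of 20 (Trp73, 0.30, adjusted p = 0.00929), both named after their values were seen. Prxl2b lost the call without EtOH 2 (0.152), EtOH 3 (0.187), 4OHT 1 (0.177), 4OHT 2 (0.149), 4OHT 3 (0.0741), EtOH_Rosi 3 (0.0592), 4OHT_Rosi 1 (0.0599), 4OHT_Rosi 2 (0.0662) or 4OHT_Rosi 3 (0.0506), and Trp73 passed without each of the 12 in turn. The smaller one-sided Fisher exact p was 0.550, and the other 0.813, so these counts do not decide the question.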
